A study of Homo sapiens with 9 samples.

How the data were processed

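Nascent DNA was sequenced from 2 human cell lines. RPE1 is a line of retinal pigment epithelial cells immortalised with telomerase, and HCT116 is a colorectal carcinoma line. Per the labels, growing cells were given a pulse of the thymidine analogue EdU, which marks DNA made during the pulse, and were sorted by flow into 3 fractions of S phase, early, mid and late. EdU-marked DNA was then pulled down with streptavidin and sequenced as single-end reads of 50 bases. RPE1 was done in 2 sets of 3 libraries and HCT116 in 1 set, giving 9 libraries. Nothing in the labels says whether the RPE1 sets came from separate cultures. For HCT116, the labels give replicate number 2 to mid and late S and no number to early S, and tie all 3 to 1 table. They were treated as 1 set, and whether they came from the same sort is not given.

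The deposited tables hold whole-number read counts in 3137207 bins, nearly all of 1 kb, with 3 count columns for each set. Per the submitters' processing notes, Bowtie2, SAMtools 1.2, bedtools 2.25 and the hg19 build were used, with no role or order given. The names of the tables in the labels point to removal of duplicate reads, and the method is not given in the sources used here. The same holds for mapping settings and the handling of reads that map to several places. The counts were not scaled to a common total before deposit, since column totals differed, from 6170299 to 22930078 reads. Reads that map to several places, collapsed repeats and a cell line's own copy number all change the count of a bin, and a share of counts within a set is less exposed to copy number than the count itself.

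The tables carry no column names. The labels tie each table to a cell line and a set, and do not say which count column holds which fraction. Columns were therefore not given to early, mid or late S, and are called libraries A, B and C by their position in the table. A letter means a position only and not a fraction. All comparisons that need a named fraction, fixed before the data were examined, were left out for this reason. They are the early against late and mid S tests in RPE1 with edgeR, with their TMM and DESeq2 alternatives and replicate block, the log2 ratio of early to late reads and its weighted index, the timing of gene lists, and depth by single fraction. Those tools were not run. The fallback fixed for this case was used, that is, the summed reads, the largest share and the correlations between libraries. Gene lists were not analysed here, because no annotation of hg19 was used here, and regions are given by coordinate alone.

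Bins of the 22 autosomes and chromosome X were summed to 50 kb windows. A window was kept with at least 25 bins holding a read, at least 50 reads over the 6 RPE1 libraries and at least 30 reads in each set. The last condition was added after the data were examined and dropped 2 windows. Of 60739 windows, 56728 were kept. Each library was scaled to the mean library total over the kept windows, and the 3 scaled values of a set were turned into shares. Even mixing, as the reference for the largest share, was a multinomial draw. The summed reads of a window were given to the libraries of its set in proportion to their totals, and were then scaled. Correlations were taken on log2 of scaled reads plus a pseudocount of 1, over windows, which are not independent replicates.

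Further measures were chosen after the data were examined. Runs of adjacent windows led by 1 library were called domains. The log2 scaled reads of a set, centred within each window, were reduced to their first principal component over autosomal windows, here called the leading axis, and divided by its autosomal SD. In each set the axis was centred on its autosomal mean. Its value does not change with the order of the columns. The sign was set so that library C of RPE1 set 1 had a positive weight and the other sets correlated above 0 with that set, so the sign of a correlation between sets carries no information. A window was called differing when HCT116 lay at least 1 SD above both RPE1 sets or at least 1 SD below both, and a region was a run of at least 5 such windows. The rule for naming regions, fixed before the data were examined, takes the 5 longest runs in each direction. Naming a run tied in length with the last of them, and the axis the rule was applied to, were chosen later. With 2 RPE1 sets and 1 HCT116 set no p-value was computed, and the difference between the RPE1 sets is the only replicate error.

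Read depth by chromosome was the share of all reads of a set on that chromosome, as HCT116 over each RPE1 set. For segments, a window's scaled reads were divided by the median of autosomal windows in the same of 50 classes of the leading axis of that set. The medians over 1 Mb were smoothed over 3 windows, and a segment needed at least 5 of them with HCT116 apart from both RPE1 sets by 0.3 on the log2 scale in 1 direction. This matching was brought in after a version without it had called 10 segments between the lines and 17 between the RPE1 sets. A weighing of technical causes for those earlier segments was dropped, since the matching selects on the same values. Runs nearly without reads were windows with HCT116 under 0.2 of both RPE1 levels, with at least 300 RPE1 reads.

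The axis and the calling of windows were tested on simulated data in which all sets had the RPE1 set 1 profile at their own depth and 200 of 56728 windows of HCT116 were moved. Moves of 1.5, 2 and 3 SD were each recovered in 100% of the windows, and 7, 6 and 5 unchanged windows were called. Only counting noise was simulated, and every move was larger than the calling threshold. The check therefore gives no rate of false calls for real sets, whose axes also vary between sorts or sets (SD of the RPE1 difference 0.180). Median reads per window and library ranged from 76 to 295. Intervals are 95% intervals, Wilson for shares and exact Poisson for counts, and cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Alternatives changed the window size, the filter, the pseudocount, the threshold, the scale of the axis, the depth and the bins with the highest 0.1% of reads.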

Results

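Replication timing in RPE1 and HCT116 cells was measured by sequencing EdU-marked DNA from 3 fractions of S phase. The 9 libraries held between 6170299 and 22930078 reads. RPE1 set 1 had 13867005, 6170299 and 15854234 reads in libraries A, B and C, RPE1 set 2 had 22930078, 16019553 and 16472082, and HCT116 had 8604034, 12276325 and 6639310. HCT116, with 27519669 reads in all, was the shallowest set, against 35891538 and 55421713 for RPE1. The letters give the position of a column, and no library could be given to a fraction. A single HCT116 set was used, so its values carry no replicate error.

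How strongly each part of the genome was taken up by 1 library was measured first. In an average 50 kb window the library with the most scaled reads held 56.9% of them in RPE1 set 1, 52.8% in RPE1 set 2 and 51.8% in HCT116. Reads mixed evenly among the libraries would have given 35.5, 35.0 and 35.7%. The RPE1 mean was 54.8% ± 2.85 (SD, n = 2), and HCT116 lay below it by little more than that spread. In RPE1 set 1, 73.7% of windows had a library with at least 50% of the reads, against 55.7% in RPE1 set 2 and 55.4% in HCT116.

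Neighbouring windows were led by the same library over long stretches. There were 5929 such domains in RPE1 set 1, 5626 in RPE1 set 2 and 4454 in HCT116, with median lengths of 250, 250 and 300 kb. Domains of at least 500 kb held 72.2 and 73.2% of the RPE1 windows and 85.1% of the HCT116 windows. HCT116 also had the lowest count at 100 kb windows, with 2768 against 4442 and 4340, and after thinning all libraries to the smallest, with 5053 against 6169 and 6461. At 20 kb windows its count, 13949, lay between the RPE1 counts of 14426 and 12535. The longest domain of every set was on chromosome X and was led by library C. It ran from 77400001 to 100100000 in RPE1 set 1, from 86800001 to 99950000 in RPE1 set 2 and from 80050001 to 95850000 in HCT116 (hg19).

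Libraries A and C each correlated best with the library at their own position in the other sets, and library B did not do so throughout. Between the RPE1 sets, Pearson's r over windows was 0.948 for A, 0.640 for B and 0.915 for C. HCT116 against the RPE1 sets gave 0.836 and 0.842 for A, 0.523 and 0.541 for B, and 0.652 and 0.668 for C. These values rest on scaled reads and not on shares, and include chromosome X. Differences in read depth between the lines therefore also enter those of HCT116. Library B of RPE1 set 1 correlated more with library A of RPE1 set 2, at 0.703, and with library A of HCT116, at 0.630, than with library B of those sets. Within a set, A and C ran against each other, with r of -0.744, -0.644 and -0.461 in RPE1 set 1, RPE1 set 2 and HCT116. The leading axis took up 95.1, 82.1 and 82.9% of the variance among the libraries of these sets. After centring within windows, the first component takes the larger part of this variance by construction. Library A had a negative and library C a positive weight in every set. The weight of library B was -0.287, 0.105 and -0.207, so the axes were not exactly the same contrast. In RPE1 set 1 the tenth of windows at the lower end of the axis had 62.0% of reads in A and 2.83% in C, and the tenth at its upper end had 13.1% in A and 70.4% in C. RPE1 set 2 had 66.2 and 15.1% at the lower end and 12.2 and 61.4% at the upper end, and HCT116 had 53.3 and 13.5% at the lower end and 16.1 and 64.2% at the upper end.

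The concordance of the RPE1 sets set the error for the comparison of the lines. On autosomes the leading axis correlated between the RPE1 sets at r = 0.984 (Spearman 0.973), and the SD of their difference was 0.180 autosomal SD. Both RPE1 sets were led by the library at the same position in 89.2% of windows, with an adjusted Rand index of 0.72. No window of 56728 differed by 1 SD between the RPE1 sets, and the largest difference was 0.924 SD. This count depended on the scale of the axis, since 3.63% of windows differed by that much after axis values were replaced by normal ranks.

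Chromosomes differed in their mean place on the axis, while their windows overlapped widely. The SD of the autosome means was 0.280 in RPE1 and 0.299 in HCT116. Windows within an autosome had SDs of 0.715 or more in every set. Chromosomes 17, 19 and 22 lay nearest the A end. Library A took 48.6, 47.0 and 47.0% of reads on chromosome 17 in RPE1 set 1, RPE1 set 2 and HCT116. On chromosome 22 it took 49.8, 47.5 and 46.7%, and on chromosome 19 it took 47.8, 44.7 and 44.4%. Chromosomes 13 and 18 lay nearest the C end among autosomes. Library C took 41.4, 40.2 and 39.3% of reads on chromosome 18, and 39.7, 38.0 and 40.9% on chromosome 13. The mean axis value of an autosome differed between the RPE1 sets by at most 0.033 SD. HCT116 differed from the RPE1 mean by more than that on 12 of 22 autosomes, 7 of them with HCT116 above and 5 below. Chromosome 6, for example, had 0.134 ± 0.00021 (SD, n = 2) in RPE1 and -0.015 in HCT116.

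**Figure D1:**
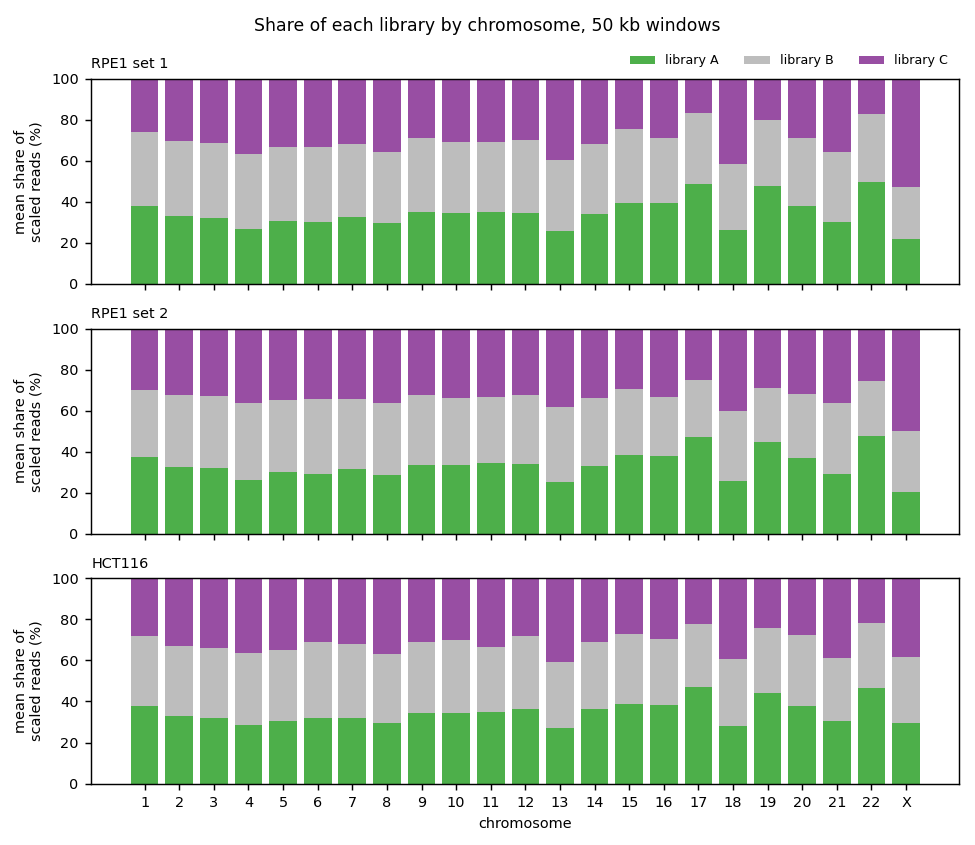
Stacked bars show the mean share of scaled reads (percent, vertical axis) in libraries A, B and C for each chromosome (horizontal axis), averaged over 50 kb windows, in 1 panel per set. Library C took 52.8 and 49.7% of reads on chromosome X in the RPE1 sets and 38.1% in HCT116, while chromosomes 17, 19 and 22 had the highest A shares in all sets.

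Chromosome X was the chromosome on which the lines were farthest apart. Library C took 52.8 and 49.7% of its reads in the RPE1 sets, above every autosome, and 38.1% in HCT116, within the autosomal range of 21.8 to 40.9%. The mean axis value was 0.808 ± 0.037 (SD, n = 2) in RPE1 and 0.333 in HCT116, a difference of -0.475. Autosomal differences ran from -0.152 on chromosome 12 to 0.130 on chromosome 21. The windows of X also spread less in RPE1, with an SD of 0.478 and 0.597 in its sets against 0.917 in HCT116, where autosomes had 0.889 to 1.06, 0.891 to 1.06 and 0.715 to 1.08. These X differences were larger than the spread between the RPE1 sets.

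Along the autosomes, HCT116 resembled RPE1 less than the RPE1 sets resembled each other. The axis correlation was 0.781 and 0.790 with the RPE1 sets, and the SD of the difference was 0.663 and 0.647, over 3 times that between the RPE1 sets. The leading library was at the same position in 68.8 and 70.1% of windows, with adjusted Rand indices of 0.34 and 0.35. HCT116 lay at least 1 SD from both RPE1 sets in 5738 autosomal windows, or 10.7%, of which 1848 were above and 3890 below, nearer the A end. With chromosome X there were 6263 such windows, or 11.04%, with 1849 above and 4414 below. With X included, 10.5% differed when normal ranks replaced SD units, and the part of differing windows with HCT116 below was 70.5%, and 57.6% with normal ranks. With these ranks 6.04% of windows were below and 4.44% above, and the split was not taken on autosomes alone. Each axis is centred on its autosomal mean. The excess of windows below therefore does not place the HCT116 autosomes as a whole nearer the A end, and it depended on the scale of the axis.

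Differing windows formed 459 regions of at least 250 kb, which covered 203 Mb. HCT116 was above RPE1 in 131 of these and below in 328. Of the latter, 1 lay inside a run nearly without HCT116 reads, on chromosome 16 from 6500001 to 6900000, and 458 regions were left without it. On chromosome X there were 36 regions, all with HCT116 below, and 1 of 525 differing X windows was above.

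The longest region with HCT116 above RPE1 was on chromosome 8, from 96750001 to 98050000, with an axis value of 1.08 in HCT116 and -0.40 ± 0.021 (SD, n = 2) in RPE1. Library C held 49.4% of its 17209 HCT116 reads after scaling, against 13.5% and 21.0% in the RPE1 sets. The next was on chromosome 9, from 16000001 to 17250000, at 0.907 in HCT116 and -1.11 ± 0.013 in RPE1. Chromosome 1 had a region from 239900001 to 241050000 with 1.40 in HCT116 and -0.77 ± 0.060 in RPE1, where library C held 59.2% against 8.51 and 19.2% of scaled reads. Chromosome 5, from 109600001 to 110750000, had 1.10 and -0.42 ± 0.037. Chromosome 7, from 41450001 to 42500000, had 1.41 and -0.64 ± 0.059.

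Of the regions with HCT116 below RPE1, the longest was on chromosome 5, from 173600001 to 175150000, with -0.82 in HCT116 and 0.945 ± 0.0024 (SD, n = 2) in RPE1. Library C held 16.2% of scaled reads there in HCT116, and 57.3 and 52.2% in the RPE1 sets. On chromosome 4, from 30150001 to 31650000, the values were -0.83 and 1.26 ± 0.025, and library A held 49.0% of scaled reads in HCT116 against 14.5 and 13.7%. A region of chromosome X from 27550001 to 28950000 had -0.36 and 1.14 ± 0.040. Chromosome 8, from 126850001 to 128150000, had -0.97 and 0.965 ± 0.016, and chromosome 7, from 143400001 to 144550000, had -0.76 and 0.921 ± 0.0095. A region of chromosome 17 from 9350001 to 10500000, with -0.75 and 0.798 ± 0.069, was as long as the last of these. Both named chromosome 8 regions lay in a segment with more reads in HCT116.

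**Figure D2:**
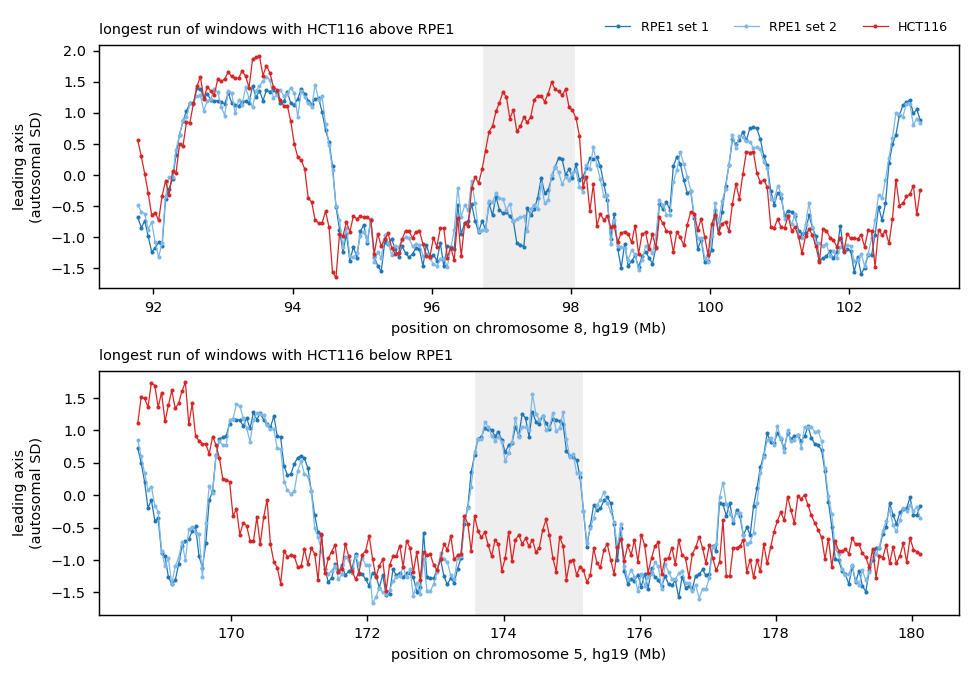
Lines show the leading axis (autosomal SD, vertical axis) by position in Mb (horizontal axis, hg19) for RPE1 set 1, RPE1 set 2 and HCT116, each point being a 50 kb window, around the longest region in each direction (grey). In the grey region of chromosome 8 HCT116 averaged 1.08 and RPE1 -0.40, and in that of chromosome 5 HCT116 averaged -0.82 and RPE1 0.945.

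Summed reads by chromosome, which need no named fraction, gave the relative depth of each chromosome in the lines. Chromosome 8 had 1.27 ± 0.022 (SD over the 2 RPE1 sets) times the read share in HCT116 that it had in RPE1, the highest of the autosomes. Chromosome 17 had 1.14 ± 0.072 times, chromosome 10 had 0.914 ± 0.000090 times, the lowest of the autosomes, and chromosome X had 0.577 ± 0.094 times. The X ratio was 0.511 against RPE1 set 1 and 0.644 against RPE1 set 2. The RPE1 sets themselves differed 1.26 times in their X share, and 0.910 to 1.11 times on autosomes. Summed reads weight the libraries of a set by their unequal sizes. With libraries weighted equally, the RPE1 sets differed 1.113 times on X and 0.974 to 1.046 times on autosomes. The ratio of HCT116 to RPE1 was then 0.595 ± 0.045 on X and 1.14 ± 0.0082 on chromosome 17.

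Within chromosomes, profile-matched depth called 6 segments with a different level in the lines, and 0 between the RPE1 sets. HCT116 had 1.41 times its own autosomal level on chromosome 8 from 67000001 to 146000000, where RPE1 had 0.976 ± 0.00013 (SD, n = 2). It had 1.45 on chromosome 16 from 79000001 to 90000000, where RPE1 had 1.00 ± 0.010. On chromosome 17 from 43000001 to 79000000 it had 1.46, against 1.04 ± 0.0024. RPE1 had 1.42 ± 0.0075 on chromosome 10 from 63000001 to 100000000, where HCT116 had 0.976. From 131000001 to 136000000 RPE1 had 1.48 ± 0.014 and HCT116 0.532. The whole of chromosome X was 1 segment, with 0.568 in HCT116 and 1.00 ± 0.0093 in RPE1. Without matching, 10 segments were called between the lines and 17 between the RPE1 sets.

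**Figure D3:**
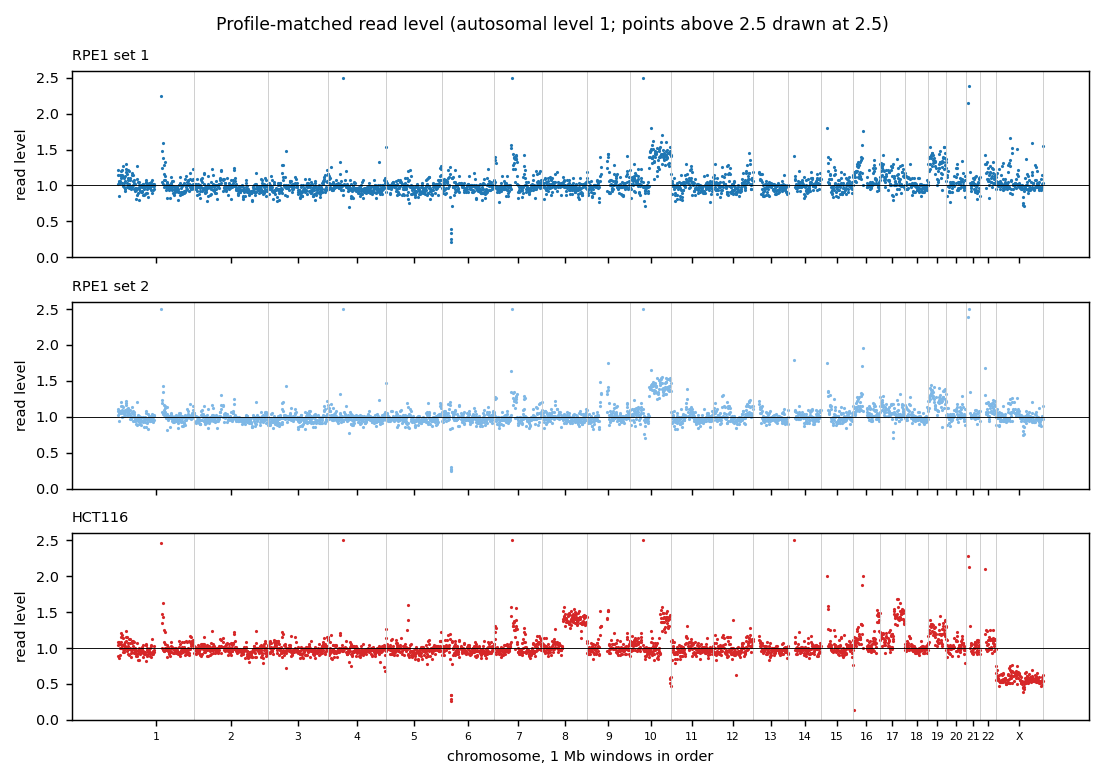
Points show the profile-matched read level (vertical axis, 1 being the autosomal level of a set, with points above 2.5 drawn at 2.5) of 1 Mb windows in order along the chromosomes (horizontal axis), in 1 panel per set. HCT116 stands at 1.41 on much of chromosome 8 and at 0.568 on chromosome X, and RPE1 at 1.42 on chromosome 10 from 63000001.

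In 3 runs, 20 windows in all, HCT116 had almost no reads where both RPE1 sets were covered. The longest was on chromosome 16, from 6250001 to 6900000, with 571 HCT116 reads against 11362 and 10844 in the RPE1 sets. The HCT116 level was 0.083 times the RPE1 level (95% interval 0.076 to 0.090, counting error of the HCT116 reads only). On chromosome X, 29650001 to 29950000 had 255 reads, at 0.096 times the RPE1 level (0.084 to 0.108), and 29550001 to 29600000 had 40 reads, at 0.103 times (0.074 to 0.140). No run of this kind was found with RPE1 low against HCT116, or between the RPE1 sets.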

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

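Reads outside the chromosomes compared were present in every library, and were picked out because no comparison used them. The mitochondrial sequence had 45997 reads in RPE1 set 1, 59167 in RPE1 set 2 and 37001 in HCT116. By library this was 0.104 to 0.158% of reads in RPE1 set 1, 0.0927 to 0.121% in RPE1 set 2 and 0.0978 to 0.177% in HCT116, so the ranges of the lines overlapped. Library A had the highest share in RPE1 set 1 and in HCT116, at 0.158% (95% Wilson interval 0.156 to 0.160%) and 0.177% (0.174 to 0.180%), and library C in RPE1 set 2, at 0.121% (0.119 to 0.123%). Haplotype, random and unplaced contigs took 1.505% of reads in RPE1 set 1, 1.57% in RPE1 set 2 and 1.88% in HCT116. Chromosome Y was also left out of every comparison, and its reads were not tallied here. No explanation was tested for the mitochondrial and contig reads.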

How the results depend on the processing

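All settings here except the 20 and 100 kb windows for the largest share and the removal of extreme bins for depth ratios were chosen after the data were examined. Of 133 alternative values, 111 stayed within the spread or, for counts and shares of windows, within 1.5 times; 22 moved, counting any value above 0 where the main value was 0, and 0 reversed. The spread was the SD of the RPE1 sets, also used for HCT116, and for the correlation of the RPE1 sets its distance from 1, an arbitrary choice. With 20 kb windows the domains numbered 14426, 12535 and 13949 in RPE1 set 1, RPE1 set 2 and HCT116, the correlation of HCT116 with RPE1 was 0.765, and 0.055% of windows differed between the RPE1 sets, against 0.0035% without the filter and 0.035% after thinning. With 100 kb windows HCT116 had 2768 domains and its correlation was 0.794. More domains in smaller windows follow from the construction. A threshold of 0.5 SD gave 30.9% differing windows (19.0% below, 11.9% above) and 1.32% between the RPE1 sets; 1.5 SD gave 3.24% (2.09% below, 1.15% above). Normal ranks gave correlations of 0.920 between the RPE1 sets and 0.723 with HCT116, 3.63% of windows differing between the RPE1 sets and an X difference of -0.426; the cause was not tested. The depth ratio of chromosome 10, whose SD was 0.000090, was 0.893 without extreme bins and 0.913 with libraries weighted equally; the cause was not tested. With each RPE1 set left out, differing windows ranged from 12.4 to 13.7%, the X difference from -0.501 to -0.449 and the X depth ratio from 0.511 to 0.644. Differing windows could only rise here, since HCT116 then had to differ from 1 RPE1 set only. The HCT116 correlation, X difference and depth ratios are means over the RPE1 sets. Leaving 1 set out could not move them beyond the SD of these sets. Their leave-out values, counted among the 111, therefore say nothing on stability. No paired analysis was possible because the columns carry no fraction and no result came from a test. The fraction-based alternatives fixed before the data were examined were not run. Thinning all libraries to 6016614 reads left 10.7% differing; the effect of depth at other window sizes was not tested.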

Other observations

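The tests of depth difference, X slope, low RPE1 coverage on chromosome 16 and the chromosome 10 stretch were chosen after the values they rest on had been seen in substance; the others were set down before their result. The chromosome 10 test was first run on part of the stretch, then on all of it, and then on each part with the spread of other autosomes. All measures on the leading axis were chosen after the data were examined.

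The 5 Mb at the outer end of an autosomal arm lay below the rest of the arm, nearer the A end, in 22 of 39 arms in RPE1 set 1, 23 in RPE1 set 2 and 28 in HCT116, and 21 arms did so in all sets. The 5 Mb beside the longest gap without reads lay above the rest of the arm in all sets in 22 arms and below it in all sets in 9. It lay below in 11, 9 and 15 arms in RPE1 set 1, RPE1 set 2 and HCT116.

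Some stretches had levels away from 1 in all sets. Chromosome 6 from 29000001 to 34000000 was at 0.303 and 0.296 in the RPE1 sets and 0.330 in HCT116. On chromosome 10 from 100000001 to 131000000 both lines were raised, with 1.42 ± 0.0085 (SD, n = 2) in RPE1 and 1.40 in HCT116. Such a level was not particular to this stretch. RPE1 and HCT116 had 1.34 and 1.34 on chromosome 7 from 56000001 to 69000000, and 1.40 and 1.48 on chromosome 9 from 66000001 to 71000000. They had 1.37 and 1.46 on chromosome 16 from 28000001 to 34000000, and 1.35 and 1.28 on chromosome 19 from 3000001 to 19000000.

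Chromosome X lay nearer the C end in RPE1 than in HCT116. Sequencing depth was argued against, since thinning every library to the smallest left a difference of -0.472, and so were a few repeat-rich windows, since 68.5% of X windows had HCT116 below both RPE1 sets, against at most 48.8% on an autosome. A difference in read depth between the lines stayed open. The 5 autosomal segments with such a difference shifted by -0.318 to 0.282. All went toward the C end where HCT116 had more reads and toward the A end where it had fewer, as on X. Only the 2 shortest, of 5 and 11 Mb, shifted by more than 50% of the size of the X difference. Blocks of the 5 Mb length on other autosomes had an SD of 0.304. The longer segments shifted by 0.136, -0.058 and 0.051. The value of -0.058, on chromosome 10, was no lower than the -0.070 on the rest of that chromosome. These shifts therefore cannot decide the question. A further X copy in RPE1 that replicates around library C stayed open as well. Such a copy would itself be a difference in read depth, so these 2 explanations overlap. X stood at 1.00 of the autosomal level in RPE1 and at 0.568 in HCT116, which does not show when a copy replicates. The slope of RPE1 on HCT116 over X, 0.443 against 0.662 to 0.943 on autosomes, follows from the smaller RPE1 spread on X that prompted the idea, and lends it no support.

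HCT116 was nearly without reads over the stretch of chromosome 16 from 6250001 to 6900000. Sequence that takes few reads in any library was argued against: the lower RPE1 level there was 0.997 of the autosomal level and no window was below 0.884, while the 300 reads by which windows were chosen correspond to 0.204. The remaining HCT116 reads may come from a few bins that take reads from elsewhere, since 58.0% of them lay in the tenth of 1 kb bins with most of them, against 33.2% for reads spread like those of RPE1. A loss of the stretch in HCT116 is a hypothesis that was not tested.

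RPE1 had more reads than its autosomal level on distal chromosome 10. Whether a further copy there replicates as the RPE1 X does stayed open. The needed difference of HCT116 from RPE1 was set at -0.228 or lower, against -0.070 on the rest of the chromosome. This value is that of the rest lowered by an assumed part of the X difference of -0.475. A larger assumed part would make the needed value lower, so the outcome rests on this choice. From 63000001 to the end the difference was -0.089, with an SD of 0.087 among blocks of that length on other autosomes, so the needed value lay within 2 SD. By part it was -0.058 from 63000001 to 100000000, -0.093 from 100000001 to 131000000, where both lines were raised, and -0.318 from 131000001 to 136000000, where the SD of blocks was 0.304. In this last part HCT116 was itself lowered, at 0.532 of its own level, while RPE1 was at 1.48. The difference there cannot be given to RPE1 alone. A biological explanation was not tested.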
